A study of Mus musculus with 33 samples.

How the data were processed

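Quadriceps RNA of 33 libraries was measured by RNA sequencing: 17 from WT and 16 from Actn3 KO mice, 20 after dexamethasone and 13 after saline, at 3 h or 24 h. Groups came from the genotype, treatment and time labels. The deposited files give, per the labels, raw read counts per gene symbol for 23420 genes, 1 file per library. The submitters' processing notes name STAR and HTSeq without a version, limma 3.40.6 and the mm10 genome; the role of each tool, the annotation and the strand setting are not given in the sources used here. Per the labels' protocols the libraries came from an unstranded TruSeq RNA kit, so reads of genes that overlap on opposite strands cannot be told apart. Of 450 named genes 446 were found in the reference gene table (GRCm38), and 10 of these share 20% or more of their exon bases with another gene. Those that the results name are Sox4 (54.6%) and Mybph (36%).

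The authors also deposited tables of 11 comparisons, with log2 fold changes or coefficients and with p-values and adjusted p-values per gene, per the file headers. Their design, contrast coding and filter are not given in the sources used here, and they were used only to set the authors' deposited values beside the fit.

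Each count file ends with 2 lines that are no genes, which were left out of library totals and tests. Reads assigned to no feature made 24.6 to 33.2% and ambiguous reads 0.188 to 0.3% of all counted reads. Gene counts per library ran from 19.7 M to 42.8 M, and 15199 to 16111 genes had at least 1 count. The 10 most abundant genes held 21.6 to 30.1% of the counts. Counts were compared in the 55 pairs of libraries within a group, and no pair was close enough to be the same library sequenced again (chi-square per degree of freedom 11.5 or more). Pairs across groups were not compared.

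Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 8 groups, which left 13955. Libraries were scaled by TMM, whose factors ran from 0.932 to 1.09, and 1 quasi-likelihood model with a mean per group was fitted over all 33 libraries. Each contrast of group means was tested with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The 12 contrasts were dexamethasone against saline in each genotype and time, the genotype by treatment interaction at each time and as their mean, KO against WT in saline and over all strata, the treatment by time interaction in each genotype, and saline at 24 h against 3 h. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Interaction values are KO minus WT, and time values 24 h minus 3 h. No paired analysis was possible because the labels give no replicate numbers. Replicate numbers in the text follow the order in which the libraries are listed.

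Gene lists were fixed before the data were examined, as were the groups, contrasts, tests, other settings and the rule for named genes. There were 31 lists with 537 genes, of which 520 are in the files and 500 were tested. They cover glucocorticoid receptor targets, atrophy genes, the proteasome, autophagy, insulin and mTOR signalling, fast and slow fibre genes, Z-disc proteins, calcineurin signalling, glycolysis, oxidative phosphorylation, fatty acid and amino acid genes, the clock, inflammation, interferon, myogenic genes, matrix, and immediate early and heat shock genes. Cell type lists cover macrophages, neutrophils, endothelium, fibroblasts, adipocytes, smooth muscle, satellite cells, Schwann cells and tendon. The 28 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 28 lists of a contrast. Of the 336 list tests 74 were called, and 7 of these with an estimated correlation. They are the glucocorticoid receptor targets in both genotypes at 3 h and in both time interactions, the inflammatory list in WT at 3 h, and the fast fibre list in both genotype contrasts, whose calls rest on Actn3 itself. Of the other lists the mitochondrially encoded genes are absent from the files (0 of 15), and 3 lymphocyte and 4 erythroid genes were tested, too few for a list test. A list score in a library is the mean over members of log2 CPM (prior count 2) minus the mean of all libraries.

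Named genes are Actn3, then the 10 with the largest rise and the 10 with the largest fall in each dexamethasone contrast and in the saline genotype contrast. These had to be called, have a mean log2 CPM of 1 or more and have no overlap between the groups' libraries. For the time contrasts the 5 largest each way were taken without the overlap condition. Each list gave the 4 members with the smallest p, and each interaction the 10 genes with the smallest p. Genes known only by a clone or model number were counted and not named. Fewer were printed where the order of the rule was kept.

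The edgeR test was checked on simulated counts with known changes for KO at 24 h. It found 90% of 100 genes changed 2-fold and 58% of 100 genes changed 1.5-fold, with 5 false calls, and for the interaction at 24 h 74% and 27% with 10 false calls. The changed genes were drawn from those with a mean of 1 CPM or more, so these shares do not cover genes below that level. In the same simulation of KO at 24 h a list of genes all raised 2-fold was called and 0 of 27 unchanged lists were. Genes were drawn independently there, so this says nothing on lists whose genes vary together between libraries.

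The other settings fixed at that point were relative log (RLE) scaling, scaling by totals only, no filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, the library name series as a covariate, a false discovery rate of 0.01, and leaving out each library. Of the libraries, 28 carry names of the ML1715 series and 5 of the ML1716 series, and what the series stand for is not given in the sources used here. The 5 are KO dexamethasone 3 h replicate 5, KO dexamethasone 24 h replicates 4 and 5, WT saline 24 h replicate 4 and WT dexamethasone 24 h replicate 5. The 45S ribosomal RNA gene Rn45s held 1.46 to 4.19% of the counts in the 28 and 3.14 to 11% in the 5. After seeing the data, further settings were added, namely leaving out the 5 ML1716 libraries, limma-voom with sample weights, leaving out Rn45s, and leaving Actn3 out of the lists that hold it for the genotype contrasts.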

Results

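RNA was sequenced from the quadriceps muscle of adult male C57BL6 mice that were wild type (WT) or lacked Actn3 (KO), the gene for alpha-actinin-3, an actin-crosslinking protein of the Z-disc in fast muscle fibres. Each mouse had a single intraperitoneal injection of dexamethasone sodium phosphate, a synthetic glucocorticoid, at 20 mg/kg, or of saline, and muscle was taken 3 h or 24 h later. The series asks whether alpha-actinin-3 deficiency alters how muscle answers a glucocorticoid. There were 33 libraries in 8 groups, 17 WT and 16 KO. Each of the 4 dexamethasone groups held 5 libraries. The saline groups held 3 libraries each in WT at 3 h, KO at 3 h and KO at 24 h, and 4 libraries in WT at 24 h. Gene counts per library ran from 19.7 M to 42.8 M with a median of 29.9 M. They ran from 20.1 M to 35.4 M in saline and from 19.7 M to 42.8 M in dexamethasone libraries. The labels do not say outright that each library is a separate animal, so the tests measure the spread between libraries.

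Actn3 (chromosome 19, 4861216 to 4877909, GRCm38) separated the genotypes in every library. In WT its mean was 7872 CPM (normalised read count; SD 131, n = 3) in saline and 8726 CPM (SD 894, n = 5) in dexamethasone at 3 h, and 8170 CPM (SD 825, n = 4) and 8011 CPM (SD 790, n = 5) at 24 h. In KO the means were 58.4 CPM (SD 7.56, n = 3), 66.4 CPM (SD 11.8, n = 5), 60.1 CPM (SD 7.7, n = 3) and 46.8 CPM (SD 9.45, n = 5) in the same order. The log2 difference in saline was -7.08 ± 0.144 (SE, n = 6 KO and 7 WT), with an edgeR adjusted p of 2.37e-28. Dexamethasone did not change Actn3 past the threshold in any of the 4 groups, with log2 values of 0.15 ± 0.141 in WT and 0.18 ± 0.143 in KO at 3 h, and -0.03 ± 0.129 and -0.36 ± 0.142 at 24 h.

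**Figure D1:**
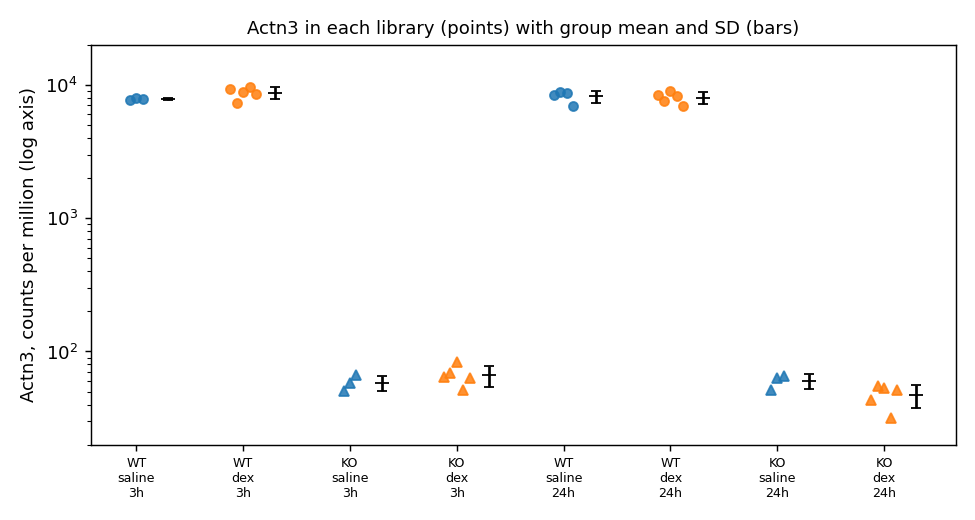
Actn3 level in each of the 33 libraries (points, CPM on a log axis) with the mean and SD of each of the 8 groups. WT group means lie between 7872 and 8726 CPM and KO group means between 46.8 and 66.4 CPM.

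At 3 h after dexamethasone, WT muscle had far higher levels of Sox4, a transcription factor (log2 fold change 5.62 ± 0.385, SE, n = 5 dexamethasone and 3 saline), of Lcn2, a secreted iron-siderophore-binding lipocalin (5.45 ± 0.575), and of Ddit4, an inhibitor of mTORC1 (5.30 ± 0.405, or 39.3-fold). Pnmt, the enzyme that makes adrenaline, rose by 4.68 ± 0.627 and the small GTPase Arl4d by 4.31 ± 0.238. Among the genes that fell most were Aplnr, the endothelial apelin receptor (-3.73 ± 0.221), B3galt2, a galactosyltransferase (-3.42 ± 0.251), and Bcl6b, a transcriptional repressor (-3.37 ± 0.339). Of 23 glucocorticoid receptor targets, 18 rose and 1 fell, and 4 did not pass, with the same numbers adjusted over the list alone. They included the NF-kB inhibitor Nfkbia (2.98 ± 0.183), the EGF receptor inhibitor Errfi1 (2.88 ± 0.202) and Hif3a (2.05 ± 0.224), and the list test gave adjusted p = 2.53e-23, and adjusted p = 0.000677 with an estimated correlation.

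Interferon, inflammatory and endothelial genes were called lower as lists at this time in WT. None of the 25 interferon and antigen presentation genes rose and 12 fell, with 12 also adjusted over the list alone, among them the transcription factor Irf1 (-1.92 ± 0.122) and the guanylate-binding protein Gbp2 (-1.73 ± 0.176). This list had adjusted p = 3.46e-09, and adjusted p = 0.0649 with an estimated correlation. Of 18 inflammatory cytokine and NF-kB genes 8 fell and 1 rose, the same over the list alone, including the nitric oxide synthase Nos2 (-1.62 ± 0.211) and the adhesion molecule Icam1 (-1.70 ± 0.248). Its test gave adjusted p = 3.61e-05, and adjusted p = 0.0201 with an estimated correlation. Of 10 endothelial markers 5 fell and 1 rose (5 and 2 adjusted over the list alone), such as the VEGF receptor Kdr (-1.77 ± 0.139) and Egfl7 (-1.52 ± 0.131). The set had adjusted p = 0.000435, and adjusted p = 0.221 with an estimated correlation. The clock list of 19 genes, 3 higher and 6 lower (3 and 7 over the list alone), was lower as a set. Tested as a set, these genes had adjusted p = 0.0193, and adjusted p = 0.232 with an estimated correlation. In it the repressors Bhlhe40 (-1.60 ± 0.145) and Bhlhe41 (-1.51 ± 0.165) fell and Npas2, a partner of Arntl, rose (2.59 ± 0.445).

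At 3 h in WT 5 of 20 genes of amino acid and glutamine handling rose and 0 fell, the same over the list alone, led by the transporters Slc7a8 (2.40 ± 0.211) and Slc7a5 (1.56 ± 0.238). As a set they had adjusted p = 0.00195, and adjusted p = 0.239 with an estimated correlation. Of 26 fatty acid genes 5 rose and 2 fell, the same over the list alone, including the mitochondrial carrier Ucp2 (1.88 ± 0.163) and the nuclear receptor Ppard (1.26 ± 0.165). Camera gave the list adjusted p = 0.0151, and adjusted p = 0.728 with an estimated correlation. The oxidative phosphorylation list was higher as a set (median log2 0.21 over 27 genes, adjusted p = 0.044, and adjusted p = 0.728 with an estimated correlation), with no member past the threshold either way (1 higher without WT dexamethasone replicate 1 and 2 without replicate 3). Its call was lost without WT saline replicate 1 (adjusted p = 0.105) or WT dexamethasone replicate 2 (0.0933), 4 (0.053) or 5 (0.0857), and the fatty acid call without WT saline replicate 1 (0.0543) or WT dexamethasone replicate 5 (0.0857). Without WT saline replicate 3 the fatty acid list had 4 called members instead of 7. Outside the called lists, the FoxO factor Foxo1 (1.36 ± 0.156) and Klf15 (1.21 ± 0.176) rose, among 4 atrophy genes of 20 that rose and 2 that fell (5 and 2 over the list alone; list adjusted p = 0.0985). Myod1, the myogenic determination factor, fell (-1.93 ± 0.25), and so did the satellite cell factor Pax7 (-1.72 ± 0.281), without a call of either list (adjusted p = 0.333 and 0.885). In WT at 3 h edgeR called 2072 genes of 13955 tested, 943 higher and 1129 lower, of which 387 and 422 changed at least 2-fold. Without the 5 libraries of the ML1716 name series, none of which is in these groups, the count was 2760, with 99.6% of the calls kept. The share of called genes that were higher, 45.5%, was 33.2% when libraries were scaled by their totals alone, and limma-voom with sample weights called 3221.

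In KO muscle at 3 h Lcn2 rose by 5.61 ± 0.584 (log2, SE, n = 5 dexamethasone and 3 saline), Odf3l2 by 5.38 ± 0.435, Ddit4 by 5.24 ± 0.401 and Sox4 by 4.96 ± 0.369. Pnmt rose by 4.39 ± 0.629. Aplnr fell (-3.95 ± 0.225), as did Bcl6b (-3.28 ± 0.341), the protocadherin Pcdh18 (-3.16 ± 0.22) and the prostacyclin receptor Ptgir (-3.03 ± 0.188). Of the 23 glucocorticoid receptor targets 18 rose and 1 fell (19 and 1 adjusted over the list alone), with Nfkbia at 3.01 ± 0.184 and Errfi1 at 2.84 ± 0.202. The test of the list gave adjusted p = 2.79e-23, and adjusted p = 0.000439 with an estimated correlation.

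The same KO libraries had 5 higher and 2 lower of 20 atrophy genes, the same over the list alone, with Foxo1 (1.35 ± 0.155), Klf15 (1.29 ± 0.176) and the muscle ubiquitin ligase Trim63 (1.93 ± 0.293) among those that rose. The list test gave adjusted p = 0.0241, and adjusted p = 0.441 with an estimated correlation. Of the amino acid list 6 rose and 0 fell (Slc7a8 1.88 ± 0.205, Slc7a5 1.56 ± 0.247), and of the fatty acid list 6 rose and 0 fell (Ucp2 1.81 ± 0.162, Ppard 1.01 ± 0.163), each the same over the list alone. Their list tests gave adjusted p = 0.0102 and 0.0071, and adjusted p = 0.441 and 0.629 with an estimated correlation. Of 31 proteasome subunits 4 rose and 0 fell (0 and 0 over the list alone). This list had adjusted p = 0.0115, and adjusted p = 0.629 with an estimated correlation. Its number of called members was 0 without KO saline replicate 1 or 2 or KO dexamethasone replicate 5, 1 without KO saline replicate 3 or KO dexamethasone replicate 4, 2 without KO dexamethasone replicate 2 and 7 without KO dexamethasone replicate 1. Of the oxidative phosphorylation list 4 rose and 0 fell, the same over the list alone. Its test gave adjusted p = 0.0251, and adjusted p = 0.629 with an estimated correlation. Here 0 members were called without KO saline replicate 2 or KO dexamethasone replicate 4 or 5, and 2 without KO dexamethasone replicate 2.

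Endothelial markers in KO at 3 h gave 2 higher and 4 lower (2 and 5 over the list alone; Kdr -1.89 ± 0.138, Egfl7 -1.52 ± 0.13). The set had adjusted p = 0.00112, and adjusted p = 0.319 with an estimated correlation. The inflammatory list gave 1 higher and 7 lower, the same over the list alone, with the interleukin-1 receptor Il1r1 up (1.40 ± 0.17) and the NF-kB inhibitor Tnfaip3 down (-1.49 ± 0.186). Tested as a set, these genes had adjusted p = 0.00845, and adjusted p = 0.285 with an estimated correlation. The interferon list gave 2 higher and 7 lower, the same over the list alone (Irf1 -1.58 ± 0.122, Ifit2 -0.85 ± 0.129). As a set they had adjusted p = 0.0147, and adjusted p = 0.629 with an estimated correlation. The clock list gave 3 higher and 7 lower, the same over the list alone (Bhlhe40 -1.33 ± 0.145). Camera gave the list adjusted p = 0.0405, and adjusted p = 0.441 with an estimated correlation. Pax7 (-2.61 ± 0.275) and Myod1 (-2.50 ± 0.257) fell, without a call of the satellite cell list (1 higher and 3 lower, adjusted p = 0.44) or the myogenic list (1 and 4, adjusted p = 0.0813). In KO at 3 h edgeR called 2428 genes, 1244 higher and 1184 lower, of which 450 and 380 changed at least 2-fold. Without KO saline 3 h replicate 2 the count was 1474 and the list calls for atrophy, proteasome, fatty acid, amino acid, clock and interferon genes were lost (each adjusted p = 0.0522), as was that for oxidative phosphorylation (0.114). The atrophy, clock and interferon calls were also lost without KO dexamethasone replicate 1 (0.0587), the clock call without KO saline replicate 1 (0.109) or KO dexamethasone replicate 3 (0.0627), the oxidative phosphorylation call without KO dexamethasone replicate 4 (0.0591) and the proteasome call without KO dexamethasone replicate 5 (0.0577). The count was 2589 without the ML1716 libraries, with 92.1% of the calls kept.

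At 24 h in WT, Lcn2 was still higher (log2 5.09 ± 0.452, SE, n = 5 dexamethasone and 4 saline), with Pnmt (2.84 ± 0.481), the receptor phosphatase Ptprf (2.81 ± 0.131) and the cell-cycle inhibitor Cdkn1a (2.77 ± 0.419). The Wnt antagonist Sfrp2 (-1.91 ± 0.278), Fam107a (-1.77 ± 0.156) and the clock gene Per2 (-1.69 ± 0.184) fell. Of 20 atrophy genes 6 rose and 1 fell, the same over the list alone. The ubiquitin ligases Trim63 (1.78 ± 0.261), Fbxo30 (0.79 ± 0.136) and Fbxo32 (1.87 ± 0.317) rose and Foxo1 fell (-0.65 ± 0.137), with list adjusted p = 0.0215, and adjusted p = 0.409 with an estimated correlation. Of 31 proteasome subunits 9 rose and 0 fell (13 and 0 over the list alone), such as Psmc2 (0.39 ± 0.0724) and Psmd8 (0.43 ± 0.111). The test of the list gave adjusted p = 2.54e-06, and adjusted p = 0.409 with an estimated correlation. Of 23 autophagy and lysosome genes 5 rose and 1 fell, the same over the list alone, with the protease Ctsl (0.56 ± 0.114) and the mitophagy receptor Bnip3 (0.57 ± 0.12) higher. The list test gave adjusted p = 0.0423, and adjusted p = 0.395 with an estimated correlation. The atrophy call was lost without WT saline 24 h replicate 4 (adjusted p = 0.0543), and the autophagy call without WT saline 24 h replicate 1 (0.073) or 4 (0.0749) or WT dexamethasone 24 h replicate 1 (0.0589) or 2 (0.0593).

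At 24 h in WT 10 of the 25 interferon and antigen presentation genes fell and 0 rose (14 and 0 over the list alone), led by the MHC class II chaperone Cd74 (-1.30 ± 0.2) and H2-Aa (-1.40 ± 0.216). This list had adjusted p = 8.75e-09, and adjusted p = 0.186 with an estimated correlation. Of 12 macrophage markers 8 fell and 0 rose (11 and 0 over the list alone), including the scavenger receptor Cd163 (-0.99 ± 0.128) and Csf1r (-0.57 ± 0.104). Its test gave adjusted p = 4.18e-07, and adjusted p = 0.395 with an estimated correlation. Of 23 extracellular matrix genes 9 fell and 1 rose (12 and 3 over the list alone), including fibronectin Fn1 (-0.85 ± 0.121) and Timp2 (-0.43 ± 0.0869). The set had adjusted p = 0.000776, and adjusted p = 0.69 with an estimated correlation. Of 10 fibroblast markers 4 fell and 0 rose (5 and 1 over the list alone), including the proteoglycan Lum (-1.05 ± 0.156). Tested as a set, these genes had adjusted p = 0.00249, and adjusted p = 0.395 with an estimated correlation. Fewer macrophage markers were called without WT saline 24 h replicate 2 (2) or 3 (5) or WT dexamethasone 24 h replicate 2, 3 or 4 (4 each), and 5 matrix genes, each lower, without WT saline 24 h replicate 3. The glucocorticoid receptor targets had 7 higher and 4 lower (8 and 5 over the list alone) and no list call (adjusted p = 0.115). Clock genes moved both ways, Per2 lower and Clock (1.09 ± 0.139) and Nr1d1 (1.22 ± 0.224) higher, with 4 higher and 6 lower (5 and 7 over the list alone), a median of 0.03, a mean of -0.01 and no list call (adjusted p = 0.618). In WT at 24 h edgeR called 1908 genes, 942 higher and 966 lower, of which 95 and 231 changed at least 2-fold. The count was 1228 without WT saline 24 h replicate 3, and 2141 without the ML1716 libraries, with 84.7% of the calls kept. Limma-voom with sample weights called 2974, and the higher share, 49.4%, was 38.7% with totals alone.

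At 24 h in KO, Lcn2 was higher by 5.81 ± 0.553 on the log2 scale (SE, n = 5 dexamethasone and 3 saline), Pnmt by 3.39 ± 0.62, Cdkn1a by 3.22 ± 0.483 and the heat shock protein Hspa1a, whose reads cannot be told from its near-identical copy Hspa1b, by 2.83 ± 0.59. The transcription factor Zfp503 (-1.87 ± 0.229), Per2 (-1.72 ± 0.195) and the MHC class II gene H2-Ab1 (-1.69 ± 0.257) fell. Of 31 proteasome subunits 17 rose and 0 fell (27 and 0 over the list alone), including Psmc2 (0.45 ± 0.0795), Psma1 (0.75 ± 0.149) and Psma5 (0.76 ± 0.155). As a set they had adjusted p = 4.56e-14, and adjusted p = 0.248 with an estimated correlation. Of the autophagy list 3 rose and 0 fell (5 and 0 over the list alone), Ctsl (0.62 ± 0.126) and Bnip3 (0.60 ± 0.132) among them. Camera gave the list adjusted p = 0.0161, and adjusted p = 0.248 with an estimated correlation. Of the matrix list 8 fell and 0 rose (10 and 1 over the list alone), with Fn1 at -1.15 ± 0.13 and collagen Col3a1 at -1.18 ± 0.272. The test of the list gave adjusted p = 7.03e-05, and adjusted p = 0.948 with an estimated correlation. Of the interferon list 5 fell and 0 rose, the same over the list alone, with Cd74 at -1.23 ± 0.216. The list test gave adjusted p = 0.0161, and adjusted p = 0.948 with an estimated correlation. Trim63 (1.32 ± 0.285) rose among 4 higher and 1 lower atrophy genes (4 and 2 over the list alone; list adjusted p = 0.349). Of the macrophage markers Cd163 alone passed (-0.72 ± 0.138; 0 higher and 2 lower over the list alone; list adjusted p = 0.349). The glucocorticoid receptor targets, 5 higher and 2 lower (6 and 5 over the list alone), had a median of -0.09 and a mean of 0.38 with no list call (adjusted p = 0.482). In KO at 24 h edgeR called 1499 genes, 805 higher and 694 lower, of which 92 and 137 changed at least 2-fold. The count was 768 without KO saline 24 h replicate 2, which also ended the autophagy call (adjusted p = 0.0568) and left 7 called proteasome and 4 matrix genes, 879 without KO saline 24 h replicate 3, which ended the interferon call (adjusted p = 0.153) and left 3 called interferon and 4 matrix genes, and 738 when these groups were fitted alone. Without KO dexamethasone 24 h replicate 3 the autophagy list had 5 called members. Without the ML1716 libraries the count was 1335, with 66.2% of the calls kept.

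Changes in WT and KO went the same way for most called genes. At 3 h Ddit4 (5.30 in WT and 5.24 in KO), Lcn2 (5.45 and 5.61) and Aplnr (-3.73 and -3.95) had nearly equal log2 fold changes. Of the 2994 genes called in either genotype, 97% had the same sign in both, 727 were called higher in both (84.1 by chance), 778 lower in both (95.8 by chance) and 1 was called in opposite directions. Of the WT calls 72.6% were also called in KO, and 62% the other way. Pearson's r between the log2 fold changes was 0.92 across these genes, which are not independent replicates, and 0.835 across all genes tested. At 24 h 423 genes were called higher in both (54.3 by chance), 383 lower in both (48 by chance) and 0 in opposite directions. At that time 42.2% of the WT calls were also called in KO and 53.8% the other way, with r = 0.799 across the 2601 genes called in either and 0.625 across all. The WT and KO comparisons share no libraries.

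Whether the genotypes differ in their answer was tested gene by gene. At 3 h edgeR called 0 genes, with 450 at an unadjusted p under 0.05, against 5 by DESeq2 and 0 by limma-voom, and 1 by edgeR without WT saline 3 h replicate 2. The smallest p values belonged to Catsper4, a sperm calcium channel subunit (1.67 ± 0.32, SE, n = 5, 3, 5 and 3 libraries; adjusted p = 0.138), H2-Q10 (2.04 ± 0.451) and the phosphodiesterase Pde3b (1.39 ± 0.316), with adjusted p = 0.357 for the latter pair. At 24 h edgeR called 1 gene, with 844 at an unadjusted p under 0.05, against 3 by DESeq2 and 1 by limma-voom. The gene was 2310022B05Rik (0.92 ± 0.165, adjusted p = 0.0465), which rose by 0.75 ± 0.113 in WT and 1.67 ± 0.128 in KO and is named because it was the only call, after its values were seen. Next came Doc2b, a calcium sensor of vesicle fusion (1.57 ± 0.314, adjusted p = 0.127), and the sulfotransferase Sult1e1 (3.65 ± 0.777, adjusted p = 0.204). That call was lost with relative log scaling, with totals only, with the name series as a covariate, at a 1% false discovery rate and when the groups were fitted alone, and the count was 0 without any 1 of 11 of the 17 libraries. It was 4 without WT dexamethasone 24 h replicate 5, 3 without KO dexamethasone 24 h replicate 3 and 2 without WT saline 24 h replicate 1 or 3. Over both times together edgeR called 0 genes, with 1026 at an unadjusted p under 0.05, against 7 by DESeq2 and 0 by limma-voom, with edgeR calling 2 without WT saline 24 h replicate 3 and 1 without WT dexamethasone 24 h replicate 5. The smallest p there was for the zinc transporter Slc30a2 (0.92 ± 0.173, adjusted p = 0.109).

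The size of a difference that stays possible differs by gene. The 95% interval of the interaction lay within 2-fold for 2147 of the 2994 genes called in either genotype at 3 h (71.7%), and for 1959 of 2601 at 24 h (75.3%). Without the ML1716 libraries edgeR called 0, 1 and 0 genes at 3 h, 24 h and over both. By list, with 0 members called in any, the adipocyte markers had a median interaction of 1.21 at 3 h (adjusted p = 3.24e-10, and adjusted p = 0.056 with an estimated correlation) and the interferon list 0.34. This list had adjusted p = 2.26e-08, and adjusted p = 0.128 with an estimated correlation. Its genotypes differed mostly in saline at 3 h, with mean scores of 0.364 in WT and 0.00199 in KO, against -0.227 and -0.247 in dexamethasone libraries. The WT adipocyte markers had Plin1 down at 3 h (-1.45 ± 0.292), while KO had Cidec up (1.5 ± 0.391), a call lost without KO saline 3 h replicate 2 (adjusted p = 0.0579). At 24 h the macrophage markers had a median interaction of 0.58 (adjusted p = 4.34e-05, and adjusted p = 0.626 with an estimated correlation). Here too the genotypes differed more in saline, with mean scores of 0.433 (SD 0.404) in WT and 0.0656 (SD 0.241) in KO. In dexamethasone libraries of 24 h the means were -0.221 and -0.0653.

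In saline, KO differed from WT in more than Actn3. Neto2, an auxiliary subunit of kainate receptors, was lower in KO by -3.18 ± 0.262 (log2, SE, n = 6 KO and 7 WT), the potassium channel subunit Kcnf1 by -2.94 ± 0.405, the glucose transporter Slc2a3 by -2.85 ± 0.165 and the Z-band protein gene Igfn1 by -2.71 ± 0.29. Tceal7 was higher in KO (2.40 ± 0.274, on chromosome X), with the co-stimulatory receptor Cd28 (1.66 ± 0.143) and the myosin-binding protein Mybph (1.56 ± 0.26), which shares 36% of its exon bases with Adora1 on the opposite strand. Of the Z-disc proteins 6 were higher and 1, Actn3, lower (8 and 2 over the list alone), with Myoz3 (0.63 ± 0.0705) and Myot (0.66 ± 0.106) higher, and the list had a median of 0.01, a mean of -0.13 and no call (adjusted p = 0.624). Without Actn3 the other 27 were called higher (median 0.03, mean 0.13, adjusted p = 0.00587, and adjusted p = 0.865 with an estimated correlation). The fast fibre list had Actn3 as its only called member of 15 (0 higher and 1 lower, or 1 and 4 over the list alone; 4 called without KO saline 24 h replicate 3, 2 without WT saline 24 h replicate 1 or 4). Its call (adjusted p = 4.72e-08, and adjusted p = 0.0445 with an estimated correlation) rests on that deleted gene, since the other 14 had a median of -0.03, a mean of -0.02 and adjusted p = 0.826 (0.957 with an estimated correlation). Both tests without Actn3 were chosen after the results were seen.

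In saline 6 of 10 adipocyte markers were lower in KO and 0 higher (9 and 0 over the list alone), with the lipid droplet protein gene Cidea at -1.28 ± 0.272. The set had adjusted p = 9.23e-05, and adjusted p = 0.313 with an estimated correlation. Of the interferon list 6 were lower and 0 higher (9 and 0 over the list alone), with B2m, the light chain of MHC class I, at -0.43 ± 0.0877. Tested as a set, these genes had adjusted p = 2.18e-05, and adjusted p = 0.313 with an estimated correlation. The macrophage list was lower (1 member lower and 0 higher, the same over the list alone; adjusted p = 0.0226, and adjusted p = 0.894 with an estimated correlation), a call lost without KO saline 24 h replicate 2 (adjusted p = 0.0517) or WT saline 24 h replicate 2 (0.183). Its called members were 0 without KO saline 24 h replicate 2 and 2 without WT saline 24 h replicate 1, and those of the interferon list 2 without WT saline 3 h replicate 1. Called adipocyte markers fell to 1 without KO saline 24 h replicate 2, to 2 without KO saline 3 h replicate 2 or 3, WT saline 3 h replicate 1 or 3 or WT saline 24 h replicate 2, and to 3 without KO saline 3 h replicate 1, KO saline 24 h replicate 1 or WT saline 24 h replicate 3. Myostatin (Mstn), which restrains muscle growth, was lower by -1.12 ± 0.136 and the receptor kinase Musk by -1.47 ± 0.144. The satellite cell marker Calcr was higher (1.27 ± 0.288), among 2 higher and 0 lower members (3 and 0 over the list alone; list adjusted p = 0.175). In saline edgeR called 1250 genes, 561 higher and 689 lower in KO, of which 33 and 115 differed at least 2-fold, and 1654 without the ML1716 libraries, with 94.9% of the calls kept. The count was 791 without WT saline 3 h replicate 1, 809 without WT saline 3 h replicate 3, 802 without KO saline 3 h replicate 2 and 823 without KO saline 24 h replicate 2. Limma-voom with sample weights called 2013, and the higher share, 44.9%, was 33.7% with totals alone.

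Over all 4 strata, 2879 genes differed between genotypes, 1373 higher and 1506 lower in KO, of which 36 and 81 differed at least 2-fold. Actn3 was lower by -7.15 ± 0.0979 (SE, n = 16 KO and 17 WT), Mstn by -1.08 ± 0.0868 and Musk by -1.33 ± 0.0914. Genes of the oxidative phosphorylation and TCA cycle list were higher (6 and 0 lower of 27, or 8 and 0 over the list alone), with the TCA enzymes Idh3a (0.24 ± 0.038) and Sdha (0.24 ± 0.0401). As a set they had adjusted p = 0.0108, and adjusted p = 0.863 with an estimated correlation. The fast fibre list had 1 higher and 4 lower, the same over the list alone, with the troponins Tnnc2 (-0.26 ± 0.0503) and Tnnt3 (-0.25 ± 0.0556) lower beside Actn3. The call of this list (adjusted p = 1.15e-09, and adjusted p = 0.0193 with an estimated correlation) was lost without Actn3 (adjusted p = 0.628, and adjusted p = 0.919 with an estimated correlation; mean -0.04 over the other 14). Without the ML1716 libraries 3222 genes were called.

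The answer to dexamethasone changed between 3 h and 24 h. In WT, Ddit4 differed by -6.59 ± 0.493 (24 h minus 3 h, log2, SE, n = 5, 4, 5 and 3), going from 5.30 at 3 h to -1.29 at 24 h, and Sox4 by -5.08 ± 0.498. Bcl6b differed the other way, by 4.10 ± 0.445. In KO the time difference was -5.69 ± 0.499 for Ddit4, -4.88 ± 0.5 for Sox4 and 3.61 ± 0.458 for G0s2, an inhibitor of triglyceride breakdown (n = 5, 3, 5 and 3). Glucocorticoid receptor targets were less raised at 24 h in both (1 higher and 12 lower in WT, 1 and 13 over the list alone, adjusted p = 2.24e-12; 0 and 13 in KO, 1 and 15 over the list alone, adjusted p = 1.05e-18), with adjusted p = 0.0258 and 0.002 with an estimated correlation. Endothelial markers went the other way (5 higher and 1 lower in WT, 4 and 2 in KO, or 6 and 2 and 4 and 2 over the list alone), with Kdr at 2.30 ± 0.192 in WT and 2.04 ± 0.201 in KO (list adjusted p = 0.00021 and 0.0107, and adjusted p = 0.237 and 0.626 with an estimated correlation). Macrophage markers were lower at 24 h than at 3 h relative to saline (0 higher and 7 lower in WT, 0 and 3 in KO, or 0 and 9 and 0 and 4 over the list alone), with Cd163 at -1.48 ± 0.191 in WT and -1.17 ± 0.198 in KO (list adjusted p = 0.00021 and 0.037, and adjusted p = 0.64 and 0.828 with an estimated correlation). The saline libraries moved too: the mean macrophage score went from -0.00429 to 0.433 in WT saline and from 0.101 to -0.221 in WT dexamethasone libraries. In KO it went from -0.265 to 0.0656 in saline and only from -0.0386 to -0.0653 in dexamethasone libraries, so the KO difference is mostly one of saline libraries. The KO macrophage call was lost without any 1 of 8 libraries, with adjusted p up to 0.2 without KO saline 24 h replicate 3, and also without the ML1716 libraries (0.123). In WT 215 of the 409 genes called at both times were called in opposite directions (52.6%, where independent calls give 49.9%), and in KO 105 of 356 (29.5%, and again 49.9%). The WT genes include Klf10, a TGF-beta-induced repressor (-2.30 and 1.28), and the glycolysis regulator Pfkfb3 (-1.32 and 2.08), both picked after their values were seen. In all 2371 genes changed with time in WT (1235 higher and 1136 lower at 24 h) and 1499 in KO (716 and 783), and 2808 and 1724 without the ML1716 libraries. In KO the higher share, 47.8%, was 52% with totals alone, and in WT limma-voom with sample weights called 3574.

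Saline muscle at 24 h was compared with saline muscle at 3 h as the background for those time differences (n = 7 and 6). Nr4a3, an orphan nuclear receptor, was lower by -4.69 ± 0.632 (log2, SE) in saline at 24 h, and Inmt, a methyltransferase, was higher (1.32 ± 0.168). Cebpd was higher by 1.38 ± 0.341, a call lost without any 1 of 6 of the 13 libraries, with adjusted p up to 0.0933. Of the extracellular matrix list 7 were lower and 0 higher (15 and 0 over the list alone), with basement membrane collagen Col4a1 at -0.71 ± 0.119. The test of the list gave adjusted p = 3.72e-13, and adjusted p = 0.496 with an estimated correlation. Macrophage markers were higher as a list (0 members called, 7 higher and 0 lower over the list alone; 1 called without KO saline 24 h replicate 1 and 3 without WT saline 24 h replicate 1). The list test gave adjusted p = 6.27e-06, and adjusted p = 0.496 with an estimated correlation. The clock repressor Nr1d1 was lower (-0.93 ± 0.182), with no list call (adjusted p = 0.853). In all 331 genes were called, 142 higher and 189 lower, and 442 without the ML1716 libraries. The higher share, 42.9%, was 60.5% with libraries scaled by totals alone, so the main direction depends on scaling, and the count was 584 by DESeq2, 498 with only the saline groups fitted and 1059 by limma-voom with sample weights. The count ran from 123 without KO saline 24 h replicate 3 to 509 without WT saline 24 h replicate 1, and moved over 1.5-fold for 11 of the 13 libraries.

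The authors' deposited table for WT at 3 h has 2552 genes at an adjusted p under 0.05, for WT at 24 h 2170, for KO at 3 h 3012 and for KO at 24 h 3114. The log2 fold changes of the authors' deposited tables and of the edgeR fit correlated across genes at 0.955, 0.912, 0.967 and 0.935 in that order. All 1826, 1436, 2098 and 1409 genes called in both the authors' deposited table and the edgeR fit had the same sign. Both come from the same series of libraries, so this says little. Across all genes in both, 86.4, 84.6, 89.4 and 88.8% had the same sign. At 24 h the authors' deposited tables have more genes in KO than in WT, where the edgeR fit had fewer (1499 and 1908). The authors' deposited table for the genotype by treatment interaction has 0 genes past that level, with 916 at an unadjusted p under 0.05, where edgeR, DESeq2 and limma-voom called 0, 7 and 0 over both times. The authors' deposited table for the interaction with treatment and time has 3, which are Tmem100 (-2.00), Mras (0.85) and Cbx8 (1.16), named after their values were seen. In the authors' deposited table for genotype 2734 genes pass and Actn3 has a log2 value of -7.17.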

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

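Of the tests in this part, the share of called genes within 20 Mb of Actn3 was chosen before its result was seen; the count outside that segment, the smaller windows, the adipocyte tests, the tests of opposite changes, the fits without the ML1716 libraries and the other splits of the libraries, with the fits of 1 such split by name series, were chosen after.

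In saline, 1250 genes were called between KO and WT. A segment of chromosome 19 carried along with the null allele could account for calls near Actn3, but within 20 Mb 25 of 257 tested genes were called (9.73%) against 1223 of 13650 elsewhere (8.96%), an odds ratio of 1.09 (95% interval 0.691 to 1.67, two-sided Fisher exact p = 0.659). Outside that segment 1224 genes were called, 1 of them without a position, against at most 7 in the other splits of the libraries, so few calls lie in the segment, but its effects on distant genes and the lack of Actn3 cannot be told apart, since both go with genotype in every library. Within 0.5 Mb 5 of 26 genes were called (odds ratio 2.42, 0.712 to 6.61), so a passenger effect on the few nearest genes stays open. The lack of Actn3 itself is the biological explanation that the design gives, and it stays open and untested against these effects and a background difference elsewhere in the genome.

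At 3 h the adipocyte list had a median interaction of 1.21 (adjusted p = 3.24e-10, and adjusted p = 0.056 with an estimated correlation), and all 10 markers, 0 of them on another list, were positive. Its mean score was 0.695 (SD 0.512, n = 3) in WT saline and 0.232 (SD 0.386, n = 5) in WT dexamethasone libraries, and -0.495 (SD 0.34, n = 3) and 0.261 (SD 0.289, n = 5) in KO; Cfd, the most abundant marker, averaged 148, 135, 64.0 and 139 CPM in the same order of groups. Different shares of fat tissue in the pieces of muscle may account for this. The other 9 genes with the smallest interaction p had a median within-group correlation of 0.482 with the score, against 0.244 at the top 2.5% of 10000 random sets. With the score in the model these 9 genes kept a median of 0.612 of their estimate (95% interval 0.406 to 0.907, from resampling genes). But they were mixed: Pla2g4e, Catsper4, Slc30a2 and Ntrk3 kept 93.1, 90.7, 87.6 and 83.2% and H2-Q10 61.2%, and Adora1, Pde3b, Kcnk3 and Prkar2b 51, 42.2, 40.6 and 34.7%. Over the set fat content and a genotype difference in the answer therefore cannot be told apart. The name series argues less as a source, since without the ML1716 libraries the list kept its call (adjusted p = 4.86e-10).

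In WT 215 genes were called in opposite directions at 3 h and 24 h, such as Ddit4 (5.30 and -1.29) and Slc7a8 (2.40 and -1.37), and 141 would be if calls at the 2 times were independent, but genes called the same way were also above independence (111 against 63.7 higher, 83 against 78.2 lower), so the opposite ones were 52.6% of the 409 called at both times against 49.9%. In KO there were 105, below the 130 of independent calls, and 52 were in both. A shift of the saline libraries between collection times could produce such genes, but it made up a median of 0.159 of their change (95% interval 0.136 to 0.198). That interval came from resampling genes and does not cover the spread between the 3 and 4 WT saline libraries. The name series as the cause would need the number without the ML1716 libraries to be no higher than independent lists give. It was 286, with 212 for independent lists and 188 of the 215 among them. The number for independent lists rose too, from 141 to 212, so the rise from 215 to 286 itself says nothing. The share of 0.159 and the 188 of 215 genes that stayed argue against these explanations as the whole cause, the former without an interval over libraries. But the counts do not show opposite changes beyond genes called more readily at both times. A response that turns over stays an open hypothesis for single genes, found and tested on the same data.

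In 13 of 160 groups of values 1 library stood apart from the rest of its group, where chance gives about 8. Only groups of 4 or 5 libraries were checked, so WT saline 3 h, KO saline 3 h and KO saline 24 h were not. In KO saline 24 h, outside this check, Rn45s held 4.19% of counts in replicate 2 and 2.02 and 1.91% in replicates 1 and 3. Rn45s held 4.06% of counts in WT saline 24 h replicate 4 (others 1.63 to 1.82%), 4.33% in WT dexamethasone 24 h replicate 5 (1.46 to 1.85%) and 11% in KO dexamethasone 24 h replicate 5 (2.09 to 3.14%). In WT dexamethasone 24 h replicate 5 the calcineurin score was -0.102 (others 0.0229 to 0.0527), the inflammatory score 0.413 (-0.112 to -0.0126), the neutrophil score 1.51 (-0.37 to -0.23) and the endothelial score 0.0581 (0.216 to 0.263). In WT saline 24 h replicate 2 the amino acid score was 0.152 (others -0.0646 to -0.038) and the neutrophil score 1.39 (-0.787 to -0.422). The satellite cell score was -0.484 in WT saline 24 h replicate 4 (others -0.0161 to 0.0494), and the smooth muscle score -0.26 in KO dexamethasone 24 h replicate 4 (-0.0764 to -0.0187). The fast fibre score was 0.303 in WT dexamethasone 24 h replicate 1 (others 0.16 to 0.196), and the calcineurin score 0.0493 in WT dexamethasone 3 h replicate 1 (-0.117 to -0.073).

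Answers that differed between groups by a test of the difference were 2310022B05Rik at 24 h (KO minus WT 0.923), 2371 genes between times in WT and 1499 in KO, and 16 list tests between genotypes, of which 0 kept an adjusted p under 0.05 with an estimated correlation. At 3 h these lists were the interferon list (median 0.336, adjusted p = 2.26e-08), the adipocyte list and the tendon list (median -0.573, adjusted p = 0.000488). At 24 h they were the macrophage list (0.583, adjusted p = 4.34e-05), the proteasome (0.158, 0.00114), the interferon list (0.233, 0.00168), the adipocyte list (0.616, 0.0346), insulin and mTOR signalling (-0.134, 0.0346), smooth muscle (-0.247, 0.0455) and endothelium (-0.124, 0.0462). Over both times they were the interferon list (adjusted p = 3.5e-08), the adipocyte list (6.36e-08), the proteasome (0.00112), the macrophage list (0.00225), the tendon list (0.00457) and insulin and mTOR signalling (0.00926). The interferon difference lay mostly between the saline groups. In saline its mean score was 0.364 in WT and 0.00199 in KO at 3 h, and 0.411 and 0.176 at 24 h. In dexamethasone libraries it was -0.227 in WT and -0.247 in KO at 3 h, and -0.0988 and -0.0811 at 24 h. The mean macrophage score at 24 h was 0.433 in WT and 0.0656 in KO saline, and -0.221 and -0.0653 in dexamethasone libraries. Without the ML1716 libraries the calls for the proteasome at 24 h and over both times, for insulin and mTOR signalling, smooth muscle and endothelium at 24 h and for tendon over both times were lost, and the same 4 calls at 24 h were lost with the name series as a covariate (the adipocyte call at 24 h held in both). Leaving out single libraries also ended calls at 24 h (adjusted p without each in parentheses, replicates of 24 h groups). The proteasome call was lost without KO saline replicate 2 (0.0571). The insulin and mTOR signalling call was lost without KO saline replicate 2 (0.0833) or 3 (0.0513), KO dexamethasone replicate 3 (0.0563) or 4 (0.0552), WT saline replicate 3 (0.0882) or 4 (0.096) or WT dexamethasone replicate 1 (0.0563). The endothelial call was lost without KO saline replicate 1 (0.183) or 2 (0.0833), KO dexamethasone replicate 3 (0.064), 4 (0.142) or 5 (0.118), WT saline replicate 2 (0.177) or WT dexamethasone replicate 1 (0.0616), 2 (0.0548) or 4 (0.0675). The adipocyte call was lost without KO saline replicate 2 (0.134), WT saline replicate 2 (0.133) or 3 (0.0882), WT dexamethasone replicate 3 (0.087) or 4 (0.0569) or KO dexamethasone replicate 5 (0.061). The smooth muscle call was lost without KO saline replicate 2 (0.0833) or 3 (0.117), WT saline replicate 2 (0.211), WT dexamethasone replicate 1 (0.0563) or 4 (0.0675) or KO dexamethasone replicate 4 (0.149). Over both times the macrophage call was lost without WT saline 24 h replicate 2 (0.0521).

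The libraries of each comparison were also split in other ways into groups of the same sizes. For WT at 3 h 1 of 56 splits, the real one, gave as many genes (2072, highest other 298), for KO at 3 h 1 of 56 (2428, highest other 856) and for KO at 24 h 1 of 56 (1499, highest other 875). For WT at 24 h it was 1 of 100 (1908), and the highest other, 1893, put WT dexamethasone 24 h replicate 5 with the 4 saline libraries. For KO against WT it was 1 of 100 in saline (1250, highest other 7) and 1 of 100 over all strata (2879, highest other 95). For time it was 1 of 100 in WT (2371, highest other 3), in KO (1499, highest other 7) and in saline (331, highest other 2). In each of these 9 comparisons under 0.05 of the splits tried gave as many genes, which argues against chance without excluding it. In the dexamethasone comparisons the highest other split put all saline libraries on the dexamethasone side. Such a split holds part of the real difference with its sign turned. With 56 splits the share cannot fall under 1 of 56. Where 100 splits were used, they were drawn from more possible ones. A split not tried may thus give as many, above all for WT at 24 h. For the genotype by treatment interaction at 24 h 14 of 100 splits gave as many genes (1, highest other 68). But these splits exchanged genotype labels within each treatment and time. The genotype difference itself can thus enter the interaction of a split, so they cannot tell whether the call is chance. Chance is not excluded. At 3 h and over both times edgeR called 0 genes, so that all 100 of 100 splits gave as many was fixed beforehand and says nothing (highest other 1 and 8). The split with 68 genes put all 3 ML1716 dexamethasone libraries of 24 h on the WT side and the ML1716 saline library on the KO side. In 8 of the 100 splits, this one included, that series was placed at least as unevenly. This split also put KO dexamethasone 24 h replicates 1, 3, 4 and 5 on the WT side. It put WT dexamethasone 24 h replicates 1, 2, 3 and 4 on the KO side, with both genotypes on each side in saline. The genotype difference may therefore enter its count too, which was not tested. The same split gave 0 genes with the name series as a covariate and 2 without the ML1716 libraries, and the real split 0 and 1. That split was picked for its count, and over the 100 splits the rank correlation of this unevenness with the number of genes was only 0.241.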

How the results depend on the processing

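Of the settings in this part, leaving out the ML1716 libraries, limma-voom with sample weights, leaving out Rn45s and leaving Actn3 out of its lists were chosen after the results were seen, and the others before. Of 685 named gene and contrast pairs that were called, 0 reversed and 190 lost their call in at least 1 setting, and of 777 not called 175 were called in at least 1. Scaling moved the median of all genes by under 0.1 on the log2 scale, but with totals only the higher share of called genes was 33.2% in WT at 3 h, 38.7% in WT at 24 h, 33.7% for genotype in saline and 60.5% for time in saline. With sample weights the counts were 3221 in WT at 3 h, 2974 in WT at 24 h, 2013 for genotype in saline, 3574 for time in WT and 1059 for time in saline; the cause was not tested. At a false discovery rate of 0.01, by its construction, they were 917 in WT at 24 h, 1493 in KO at 3 h, 650 in KO at 24 h, 530 and 1658 for genotype in saline and over all strata, 1353 and 848 for time in WT and KO, 65 for time in saline and 0 for the interaction at 24 h. With only the groups compared, which leaves fewer libraries, they were 738 in KO at 24 h, 498 for time in saline and 0 for the interaction at 24 h; this setting has no separate value for the genotype contrast and interaction over all strata. DESeq2 gave 5, 3 and 7 genes for the interaction at 3 h, at 24 h and over both, and 584 for time in saline. The interaction count at 24 h was 0 with RLE scaling, totals only or the name series as covariate, and that over both times 1 with totals only; the cause was not tested. As each library was left out, counts ran from 1507 to 2010 in WT at 3 h, 1228 to 2247 in WT at 24 h, 1474 to 2867 in KO at 3 h, 768 to 1557 in KO at 24 h, 0 to 1, 0 to 4 and 0 to 2 for the interactions, 791 to 1418 and 2463 to 3021 for genotype in saline and over all strata, 1735 to 2758 and 1123 to 1566 for time in WT and KO, and 123 to 509 for time in saline. List calls ran from 64 to 79 as each library was left out, against 74 of 336, and were 7 with an estimated correlation and 59 with fry, 39 of them shared. With Actn3 left out, the fast fibre calls were lost in saline (adjusted p = 0.826) and over all strata (0.628), and the Z-disc list was called higher (0.00587 and 0.0075), but not with an estimated correlation (0.865 and 0.846). The correlation of WT and KO changes was 0.92 among genes called in either genotype and 0.88 under the stricter filter at 3 h, and 0.799 and 0.689 at 24 h. Depth limits genes near the floor. Standard errors and the intervals of the interaction cover the spread between libraries. The intervals for the share of the saline shift and for the adipocyte score came from resampling genes. The odds ratio intervals near Actn3 count genes. These do not cover the spread between libraries, and they treat genes as independent.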

Other observations

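At 24 h 4 of 20 immediate early and heat shock genes rose and 1 fell in WT (7 and 1 adjusted over the list alone; adjusted p = 0.0876) and 6 rose and 1 fell in KO (7 and 2; adjusted p = 0.118). The chaperone Hspa8 rose by 0.79 ± 0.143 in WT, and Hspb1 rose by 1.46 ± 0.371 in WT and 2.25 ± 0.428 in KO (log2, SE, n = 5 dexamethasone and 4 or 3 saline). Of 22 glycogen and glycolysis genes 1 rose and 3 fell in WT (the same over the list alone; adjusted p = 0.123) and 2 rose and 3 fell in KO (2 and 4; adjusted p = 0.349), with hexokinase Hk2 at -0.81 ± 0.16 in WT and the glycogen branching enzyme Gbe1 at 0.90 ± 0.164 in KO. Of 28 Z-disc genes 3 rose and 1 fell in WT (4 and 1; adjusted p = 0.115) and 4 rose and 1 fell in KO (4 and 2; adjusted p = 0.699), with Pdlim3 at 0.62 ± 0.141 in WT and Pdlim5 at 0.95 ± 0.182 in KO. Fast fibre genes gave 0 calls in WT (adjusted p = 0.665) and 1 higher and 1 lower in KO (adjusted p = 0.663), and slow fibre genes 0 calls in both (adjusted p = 0.34 and 0.862), each the same over the list alone.

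At 3 h the mTORC1 regulator Sesn1 rose in WT (1.35 ± 0.221, SE, n = 5 and 3) and KO (1.22 ± 0.218), in an insulin and mTOR list of 22 genes with 2 higher and 1 lower in WT (adjusted p = 0.249) and 3 higher and 2 lower in KO (adjusted p = 0.805, median -0.04, mean 0.21), each the same over the list alone. Calcineurin genes had 0 higher and 2 lower in WT (0 and 2 over the list alone; adjusted p = 0.209) and 0 and 3 in KO (0 and 4; adjusted p = 0.132), with Calm2 at -0.54 ± 0.118 and Nfatc4 at -0.80 ± 0.186 in WT and Nfatc4 at -1.04 ± 0.185 in KO. The myogenic list of 18 genes had 1 higher and 4 lower in both (1 and 5 in WT and 1 and 4 in KO over the list alone; adjusted p = 0.333 and 0.0813), with a median of 0.02 and a mean of -0.16 in WT. Satellite cell markers had 1 higher and 2 lower in WT (adjusted p = 0.885, tested as up with a median of -0.26) and 1 and 3 in KO (adjusted p = 0.44), each the same over the list alone, with the syndecan Sdc4 at 1.69 ± 0.139 and 1.73 ± 0.139. The potassium channel Kcnj8 fell in WT (-0.93 ± 0.132) and KO (-0.86 ± 0.131), among 9 smooth muscle and pericyte markers with 1 higher and 2 lower in WT (2 and 3 over the list alone) and 2 and 2 in KO, and no list call (adjusted p = 0.361 and 0.342). Of 8 Schwann cell markers the factor Sox10 fell in both (-1.41 ± 0.245 and -1.73 ± 0.241), with 0 higher and 1 lower in WT and 1 and 1 in KO, each the same over the list alone, and no list call (adjusted p = 0.243 and 0.44). Neutrophil and tendon markers were not called at 3 h in WT (adjusted p = 0.545 and 0.537) or KO (adjusted p = 0.413 and 0.268).

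Across all genes tested, the WT changes at 3 h and 24 h correlated at 0.0396 and the KO changes at 0.222, for contrasts that share no libraries.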
